A study of Mus musculus with 12 samples.

How the data were processed

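Poly(A)-selected libraries were prepared from total spleen RNA with a TruSeq RNA v2 kit, which does not mark strand, per the labels' protocols. The authors deposited 1 table of whole-number counts per gene for the 12 libraries. Bowtie2 2.2.0, RSEM 1.2.12 and the genome build GRCm38 are named, per the submitters' processing notes, without saying which step each served. How the deposited counts came to be whole numbers, and how reads shared between similar genes were split, is not given in the sources used here. Genes with near-identical copies, and genes that overlap a gene on the other strand, are therefore uncertain. Rounding of estimated counts had been planned and changed nothing, since the values were whole.

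The table holds 53715 gene identifiers. Of these 53620 matched a symbol in the GENCODE M21 annotation of GRCm38, which supplied coordinates and gene types; the 95 others held at most 0.0158% of a library's counts, and 17111 genes had no count in any library. Each column was matched to a sample through the sample's own description, and groups came from the sample titles. Replicate numbers run on across the groups and pair no samples. Pairs of libraries within a group were compared by a chi-square statistic over genes with at least 20 counts in the pair; its value per gene ran from 10.5 to 85.2 over the pairs, so no pair agreed within sampling noise.

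Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr by group, and robust quasi-likelihood fits (glmQLFit and glmQLFTest) over all 12 libraries; 18542 genes were tested. Log2 fold changes are fitted values, SE is the size of the fold change divided by the square root of the F statistic, and adjusted p is Benjamini-Hochberg over all genes tested, with a threshold of 0.05. CPM are counts scaled by library size after TMM. The 31 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 3 tested members (29) were tested with limma 3.58.1 by camera on log2 CPM (prior count 2, preset correlation 0.01), by camera with an estimated correlation, and by fry, which asks only whether a list's genes move one way on balance. The pancreas and fat tissue lists had 1 and 2 tested members, none past the threshold, and were not tested as lists. The median, mean and set test of a list differed in sign for 5 lists, none of them called: fatty acid oxidation and neutrophil precursors with age, resting T cells for 2DG at 10 weeks, and dendritic cells and immediate early genes for 2DG against 6 weeks. Shares of counts were compared by two-sided exact permutation tests.

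Named genes were, for the first 2 comparisons, the 6 largest rises and 6 largest falls among genes past the threshold with average log2 CPM of at least 2 and no overlap between groups, leaving out immunoglobulin and T cell receptor segments and predicted gene models (3 and 3 for the third); for the first 2 comparisons, up to 3 members past the threshold with the smallest adjusted p per main list, or else the member with the smallest p; and 9 genes fixed in advance, among them Cd8a, Il15, Tlr7, Il21, Ifng, Hk2, Slc2a1 and Sdc1. Some genes that this rule names are not reported here.

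Alternatives were DESeq2 1.42.0, median-of-ratios size factors in edgeR, no filter, a filter of at least 1 CPM in 4 libraries, fits of only the compared groups, removal of immunoglobulin genes, voom with quality weights, a test against a fold change of 1.5, and each library left out in turn. DESeq2 was run on the 36604 genes with any count and used its own filter, so its counts differ from those of edgeR in the genes covered too. The edgeR fit was tested on simulated counts with each gene's mean over the real libraries and a spread per gene shared by all groups. The wider spread of the untreated 10-week libraries (biological coefficient of variation 0.242 against 0.128 at 6 weeks and 0.114 with 2DG) was not simulated. Nor was the movement of genes together, since each gene was drawn independently. Recovery and false calls in the real comparison may therefore differ. For the comparison of 2DG with untreated spleens at 10 weeks, over 18542 genes, it recovered 26 of 67 genes changed 1.5-fold, 50 of 67 changed 2-fold and 62 of 66 changed 4-fold, with 4 false calls. Intervals on shares of a single library cover counting error only.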

Results

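RNA was sequenced from 12 mouse spleen samples in 3 groups of 4. All carried the BXSB Yaa background, a lupus-prone strain in which a segment of the X chromosome that includes Tlr7 is duplicated onto the Y chromosome, together with targeted alleles of Cd8a and Il15. One group was untreated and 6 weeks old, before symptoms. The other groups were 10 weeks old, at the symptomatic age, and were either untreated or given 2-deoxyglucose (2DG), a glucose analogue that blocks glycolysis, at 6 g/L in the drinking water. Total counts per library ran from 15596040 to 22480545 at 6 weeks, from 20692818 to 26079979 in untreated spleens at 10 weeks and from 21581820 to 23835453 with 2DG. The labels name separate samples but do not state that each came from its own mouse. The p-values therefore judge group differences against the spread between these samples, which may be technical. In the main edgeR fit that spread is estimated over all groups together. Levels are mean normalised counts (CPM, scaled by library size) ± SD of 4 libraries, and adjusted p-values are from edgeR unless another tool is named.

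Both genes named as knocked out were counted in every library. Cd8a (ENSMUSG00000053977.13, chromosome 6, 71373427 to 71379173, GRCm38), which encodes a chain of the CD8 coreceptor, had 582 to 1414 counts per library, and Il15, a cytokine that maintains CD8 T cells and natural killer cells, had 82 to 169. A count summed over a whole gene cannot separate an intact transcript from that of a disrupted allele, so these values do not check the genotype. Il15 passed in none of the comparisons. Cd8b1, which encodes the partner chain and was chosen after its values were seen, had 9 to 97 counts per library. Both ends of that range were untreated 10-week libraries: 9, 19 and 21 counts in replicates 5, 6 and 7, and 97 in replicate 8. At 6 weeks it had 40 to 48 counts and with 2DG 27 to 74. Tlr7 stood at 216 ± 30.6 CPM at 6 weeks, 206 ± 12.0 CPM in untreated spleens at 10 weeks and 188 ± 10.7 CPM with 2DG, and passed in none of the 3 comparisons (edgeR adjusted p = 0.759 with age, 0.413 for 2DG against untreated spleens at 10 weeks and 0.297 for 2DG against 6 weeks).

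The first comparison asked how untreated spleens differed between the pre-symptomatic and the symptomatic age. Cd8a fell from 61.7 ± 6.62 CPM at 6 weeks to 32.6 ± 4.45 CPM at 10 weeks, a log2 change of -0.92 with SE 0.11 (edgeR adjusted p = 0.036), and was lower in 4 of 4 libraries. It was the 1 gene of 18542 tested that passed. Igkc, the kappa light chain constant region, stood at 8355 ± 2241 and 21990 ± 7237 CPM without passing (edgeR adjusted p = 0.0934). Immunoglobulin genes took 3.85 ± 0.881% of all counts at 6 weeks and 8.75 ± 2.53% at 10 weeks, with all 4 libraries above those at 6 weeks. The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 libraries allow, and 0.0571 after Benjamini-Hochberg adjustment over 12 such tests, which misses the threshold. Mitochondrial genes took 1.95 ± 0.0701% and 1.84 ± 0.232% (exact permutation p = 0.4, adjusted 0.48); the difference was -0.115 points, and -0.23 without replicate 8 (exact permutation p = 0.0286).

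No member of the fixed gene lists passed with age over all genes tested, so the lists are given by their values, each with the adjusted p of its set test under an estimated correlation. All 14 plasma cell genes had positive log2 changes, with a median of 0.63, and 9 were higher when adjusted over the list alone (adjusted p = 0.317 with an estimated correlation). Ssr4, a component of the translocon complex of the endoplasmic reticulum, stood at 94.0 ± 14.5 and 169 ± 41.2 CPM (edgeR adjusted p = 0.0818). Among 14 effector T cell genes 13 were positive, with a median of 1.10 and 10 higher over the list alone (adjusted p = 0.26 with an estimated correlation). Eomes, a T-box factor of effector lymphocytes, stood at 2.51 ± 0.511 and 8.48 ± 3.02 CPM (edgeR adjusted p = 0.0812). Among 18 genes induced by interferon gamma 17 were positive, with a median of 0.63 and 14 higher over the list alone (adjusted p = 0.317 with an estimated correlation). In the follicular helper T cell list 6 of 13 genes were higher over the list alone (adjusted p = 0.346 with an estimated correlation), and Icos, a costimulatory receptor, stood at 4.65 ± 0.693 and 8.79 ± 1.69 CPM (edgeR adjusted p = 0.0815). Negative changes were found for 10 of 11 germinal centre B cell genes and 14 of 16 mature B cell genes, with medians of -0.42 and -0.29 (adjusted p = 0.502 for each with an estimated correlation). The untreated 10-week libraries were split in both lists. Replicate 8 had list means of 5.55 and 8.79 log2 CPM, above the 6-week ranges of 4.98 to 5.305 and 8.55 to 8.78. Replicates 5, 6 and 7 lay below those ranges, replicate 6 lowest at 3.38 and 7.94. The 10 megakaryocyte and platelet genes were all negative, with a median of -0.68 and 7 lower over the list alone (adjusted p = 0.345 with an estimated correlation). Of 12 immunoglobulin constant region genes 10 were positive and of 20 endoplasmic reticulum stress genes all were, with 8 and 11 higher over the list alone (adjusted p = 0.26 and 0.337 with an estimated correlation). The set test with a preset correlation also called glycolysis, oxidative phosphorylation, age-associated B cell, regulatory T cell and immediate early genes higher (adjusted p = 0.317, 0.502, 0.472, 0.472 and 0.317 with an estimated correlation), and marginal zone B cell and dendritic cell genes lower (adjusted p = 0.317 for each with an estimated correlation).

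The set test with a preset correlation called 16 of 29 lists with age, 11 higher and 5 lower, and 0 with an estimated correlation; fry called 3. At an unadjusted p under 0.05, which a share of 0.05 of genes would pass if none changed, edgeR counted 3179 of 18542 genes. DESeq2, run on a wider set of genes, called 682 at an adjusted p under 0.05. The untreated 10-week libraries differed widely among themselves, with a biological coefficient of variation of 0.242 against 0.128 at 6 weeks and 0.114 with 2DG, and replicate 8 had a median correlation across genes of 0.991 with the 6-week libraries and 0.98 with the rest of its own group. Without replicate 8 edgeR called 1563 genes, 858 higher and 705 lower, and without both replicates 6 and 8, a choice made after seeing the data, 2303. The call of Cd8a held without 2DG replicate 10 and without untreated 10-week replicate 8, and was lost without any 1 of the other 10 libraries, with edgeR adjusted p from 0.0509 to 0.187 in those fits; with only the compared groups it was 0.139, and against a fold change of 1.5 it was 0.725, the largest over the alternatives, the smallest being 1.10e-09 with DESeq2. The number of genes was 0 in those 10 fits.

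**Figure D1:**
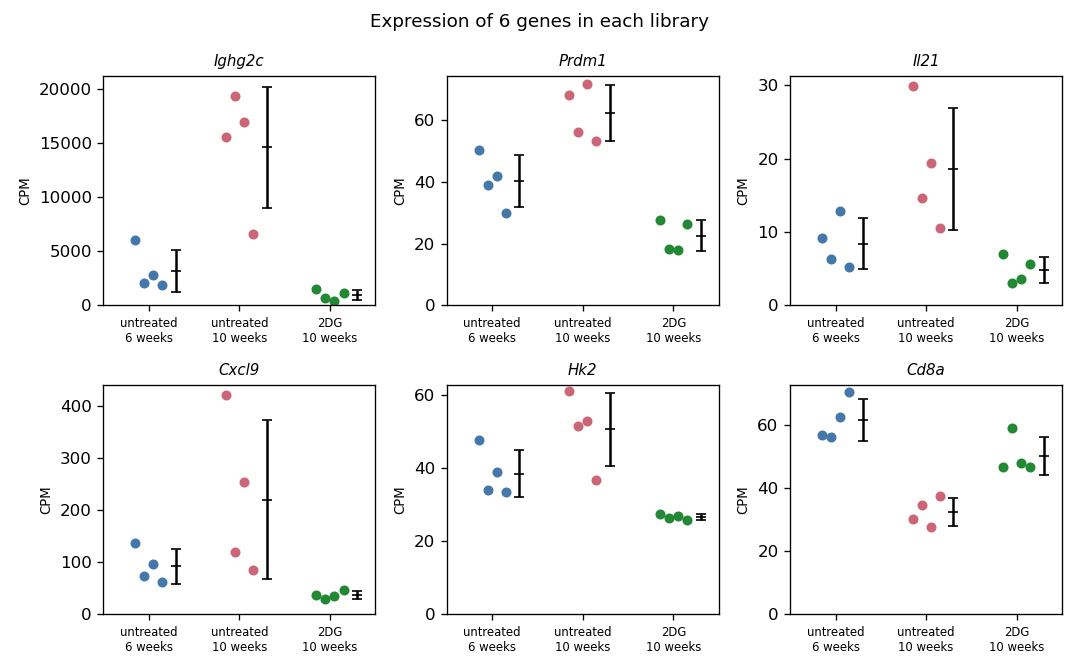
Normalised counts (CPM, linear axes from 0) of 6 genes in each library, by group; points are libraries and black bars give the mean and SD of 4 libraries. Ighg2c averaged 14600 CPM in untreated spleens at 10 weeks and 938 CPM with 2DG, and Cd8a was lower in all 4 untreated 10-week libraries than in any 6-week library.

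The second comparison asked what 2DG changed in symptomatic spleens. Of 14 plasma cell genes 12 fell, of 14 effector T cell genes 10 fell and of 18 genes induced by interferon gamma 14 fell, and none in these lists rose. Prdm1 (ENSMUSG00000038151.13, chromosome 10, 44437177 to 44528501), which encodes the Blimp-1 repressor of plasma cells, fell from 62.3 ± 8.99 to 22.5 ± 5.02 CPM (log2 change -1.47, SE 0.18, edgeR adjusted p = 0.00176), lower in 4 of 4 libraries. In all, 1376 of 18542 genes passed, 401 higher and 975 lower, among them 92 of the 247 immunoglobulin genes tested, all lower (edgeR). Immunoglobulin genes took 8.75 ± 2.53% of counts in untreated spleens and 2.49 ± 0.571% with 2DG (two-sided exact permutation p = 0.0286, adjusted 0.0571). Mitochondrial genes took 1.84 ± 0.232% and 2.17 ± 0.0318% (exact permutation p = 0.0857, adjusted 0.114), a difference of 0.33 points that was 0.445 without untreated replicate 8 (exact permutation p = 0.0286), and the 10 genes with most counts 8.14 ± 1.58% and 5.36 ± 0.188% (exact permutation p = 0.0286, adjusted 0.0571).

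All 14 plasma cell genes were lower when adjusted over the list alone, with a median log2 change of -1.22 (adjusted p = 0.132 with an estimated correlation). Xbp1, a transcription factor of the secretory pathway, fell from 596 ± 115 to 216 ± 16.2 CPM, and Irf4, which plasma cell formation needs, from 318 ± 42.1 to 164 ± 11.9 CPM. Sdc1, the surface marker CD138, fell from 60.0 ± 15.3 to 16.8 ± 3.91 CPM. Of 20 endoplasmic reticulum stress genes 13 fell and none rose, with a median of -0.71 and 14 lower over the list alone (adjusted p = 0.306 with an estimated correlation). Edem1 and Sel1l, which act in the disposal of misfolded proteins, fell with log2 changes of -1.37 and -0.77, and Creld2 fell by 1.84. Bhlha15, the secretory cell factor Mist1, fell from 40.1 ± 16.9 to 8.33 ± 2.23 CPM.

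Among 12 immunoglobulin constant region genes 6 fell, with a median of -1.37 and 8 lower over the list alone (adjusted p = 0.132 with an estimated correlation). Ighg2c (ENSMUSG00000076612.8, chromosome 12, 113285325 to 113288932) fell from 14600 ± 5584 to 938 ± 481 CPM (log2 change -3.96, SE 0.57, edgeR adjusted p = 0.00408). Ighg2b fell from 5631 ± 1780 to 602 ± 216 CPM and Igkc from 21990 ± 7237 to 5647 ± 1446 CPM. Ighm and Ighd, the IgM and IgD constant regions, did not pass and were chosen after their values were seen: Ighm stood at 12590 ± 6221 and 8199 ± 2074 CPM and Ighd at 1033 ± 102 and 1072 ± 99.4 CPM (edgeR adjusted p = 0.289 and 0.772). The heavy chain constant regions are similar in sequence, so shared reads make the split between classes uncertain.

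The other B cell lists held few calls. Among 11 germinal centre B cell genes Efnb1, a ligand of Eph receptors, rose from 13.2 ± 4.01 to 21.1 ± 2.19 CPM, and Fas, a death receptor, fell from 33.6 ± 4.74 to 22.4 ± 3.38 CPM. The 16 mature B cell genes gave no call. Of 7 marginal zone B cell genes Cd1d1 and Dtx1 rose, and 5 were higher over the list alone (adjusted p = 0.132 with an estimated correlation). Of 8 age-associated B cell genes Cxcr3, a chemokine receptor, fell from 35.2 ± 9.50 to 15.7 ± 3.88 CPM, and 6 were lower over the list alone (adjusted p = 0.293 with an estimated correlation). The call of Efnb1 was lost without 2DG replicates 9 or 11 or untreated replicates 5 or 7, that of Fas without 2DG replicates 10 or 11 or untreated replicate 5, and that of Cxcr3 without 2DG replicate 11, with edgeR adjusted p up to 0.0735, 0.0818 and 0.0542.

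In the effector T cell list the median change was -1.57, with 11 genes lower over the list alone (adjusted p = 0.132 with an estimated correlation). Tigit, an inhibitory receptor, fell from 26.7 ± 11.1 to 6.81 ± 1.63 CPM, Il10, a regulatory cytokine, from 5.36 ± 2.01 to 0.625 ± 0.231 CPM, and Gzmb, a cytotoxic granule protease, from 2.60 ± 1.92 to 0.353 ± 0.105 CPM. Untreated replicate 5 held 5.27 CPM of Gzmb against 0.853 to 2.58 CPM in the other 3, and without it the log2 change of -2.84 was -2.25. Ifng fell from 2.29 ± 1.37 to 0.481 ± 0.306 CPM. In the interferon gamma list the median was -0.96, with 15 lower over the list alone (adjusted p = 0.237 with an estimated correlation). Irf1, Irgm1 and Tap1 fell with log2 changes of -0.87, -1.01 and -0.72, and Cxcl9, a chemokine that draws CXCR3 cells, fell from 220 ± 152 to 37.4 ± 7.14 CPM. Of 24 type I interferon response genes 2 fell, among them Zbp1 with a log2 change of -1.43 (adjusted p = 0.792 for the list with an estimated correlation). Of 13 follicular helper T cell genes Icos and Il21 fell (adjusted p = 0.332 for the list with an estimated correlation). Il21 (ENSMUSG00000027718.8, chromosome 3, 37222759 to 37232636), a cytokine that acts on B cells, went from 18.6 ± 8.36 to 4.80 ± 1.82 CPM, and Icos from 8.79 ± 1.69 to 3.89 ± 0.548 CPM. The 13 resting T cell genes gave no call, and 4 of 9 regulatory T cell genes fell: Ctla4, Ikzf2, Il2ra and Tnfrsf4 (adjusted p = 0.237 for the list with an estimated correlation). The call of Ifng was lost with only the compared groups in the fit (edgeR adjusted p = 0.0545). The calls of Cxcl9, Zbp1 and Il21 were lost without 2DG replicate 10 or 11, with edgeR adjusted p up to 0.058, 0.0606 and 0.055.

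Glycolysis genes moved in both directions. Of 22 tested 6 fell and 1, Pfkm, rose, with a median of -0.37; over the list alone 14 were lower and 3 higher (adjusted p = 0.331 with an estimated correlation). Hk2 (ENSMUSG00000000628.10, chromosome 6, 82725025 to 82774454), a hexokinase that phosphorylates glucose and 2DG, fell from 50.6 ± 10.1 to 26.7 ± 0.728 CPM (log2 change -0.92, SE 0.14, edgeR adjusted p = 0.0032). Pkm, a pyruvate kinase, fell from 314 ± 80.7 to 199 ± 9.60 CPM, and Pfkfb3, which makes an activator of phosphofructokinase, from 121 ± 9.81 to 95.7 ± 6.32 CPM. Without 2DG replicate 10 or 11 both calls were lost, with edgeR adjusted p up to 0.0577 and 0.0508. Slc2a1, the glucose transporter GLUT1, stood at 49.6 ± 7.04 and 50.5 ± 3.72 CPM (edgeR adjusted p = 0.892). No gene passed among 36 of oxidative phosphorylation, 14 of the tricarboxylic acid cycle, 12 of fatty acid oxidation, 7 of the pentose phosphate pathway, 14 of Myc and the nucleolus or 29 of the cell cycle. The cell cycle list was called higher with the preset correlation, with a median of 0.22 (adjusted p = 0.792 with an estimated correlation).

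All 19 erythroid genes had positive changes, with a median of 1.04 and 15 higher over the list alone (adjusted p = 0.332 with an estimated correlation). Over all genes tested 1 passed, Hba-a2, at 0.475 ± 0.205 and 1.14 ± 0.38 CPM; its near-identical copy Hba-a1 makes this low count uncertain, and the call was lost in 10 of the 12 fits that left out 1 library, all but those without untreated 10-week replicate 7 and 2DG replicate 12 (edgeR adjusted p up to 0.143). Globin genes took 0.637 ± 0.47% and 1.37 ± 0.369% of counts (two-sided exact permutation p = 0.0571, adjusted 0.098). Of 14 monocyte genes Fcgr1, a receptor for IgG, fell from 20.4 ± 9.89 to 7.47 ± 1.17 CPM and Ly6c2 from 78.6 ± 27.0 to 34.0 ± 2.74 CPM. These calls were lost in 7 and 9 of the 12 fits that left out 1 library, among them each fit without a 2DG replicate and without untreated replicates 5 or 6 or 6-week replicate 2, and for Ly6c2 without untreated replicate 7 or 6-week replicate 3 (edgeR adjusted p up to 0.104 and 0.107). The 18 neutrophil and granulocyte precursor genes gave no call. Of 12 dendritic cell genes Clec9a, Cd209a and Zbtb46 rose (adjusted p = 0.293 for the list with an estimated correlation), and of 11 immediate early and heat shock genes Jun, Junb and Zfp36 fell (adjusted p = 0.237 for the list with an estimated correlation). Single members passed in 4 further lists: Vwf rose among 10 megakaryocyte and platelet genes (adjusted p = 0.491 for the list with an estimated correlation), Tlx1 rose among 13 of stroma and endothelium, C1qa fell among 14 of splenic macrophages and Klrk1 fell among 7 of natural killer cells. Pfkm, Cd1d1, Dtx1, Clec9a, Zbtb46, Vwf, Tlx1, C1qa, Klrk1 and the named regulatory T cell and immediate early genes were chosen after their values were seen.

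Single genes with large changes were named among genes with average log2 CPM of at least 2 and no overlap between the groups. The set left out immunoglobulin and T cell receptor genes, some of which fell further, and predicted gene models. The largest falls in it were those of Ccl8, a monocyte chemokine, Cxcl9, Iigp1, Serpina3f, Bhlha15 and Spon1. Ccl8 fell from 24.3 ± 26.6 to 0.183 ± 0.0425 CPM, with 3 to 5 counts per library with 2DG, so the size of its fitted change rests on few counts. It also rests on untreated replicate 5, at 63.2 CPM against 6.48 to 19.1 CPM in the other 3: the log2 change was -7.01, and -5.91 without that library. Among the largest rises were Cd209a, a lectin of dendritic cells, from 4.06 ± 3.36 (8.14 in untreated replicate 8, 0.991 to 5.45 in the other 3) to 18.3 ± 3.01 CPM, Mmp12, a macrophage elastase, from 2.70 ± 0.938 to 7.42 ± 1.31 CPM, and Pcp4l1, from 4.74 ± 1.12 to 10.2 ± 1.69 CPM. Igfbp5, Slc6a4 and Scand1 also rose. Cd8a rose from 32.6 ± 4.45 to 50.2 ± 5.99 CPM (log2 change 0.62, edgeR adjusted p = 0.00667). Without 2DG replicate 11 the calls of Cd209a, Igfbp5, Slc6a4 and Scand1 were lost (edgeR adjusted p = 0.0722, 0.0569, 0.101 and 0.0961), as they were for Cd209a without 2DG replicate 10 (0.0733) and for Igfbp5 without untreated replicate 5 (0.0592). Slc6a4 also lost its call without 2DG replicates 9 or 10, untreated replicates 5 or 6 or 6-week replicates 2 or 4 (edgeR adjusted p up to 0.12), and Scand1 without 2DG replicates 9, 10 or 12, untreated replicates 6 or 8 or 6-week replicates 2 or 4 (up to 0.0945).

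**Figure D2:**
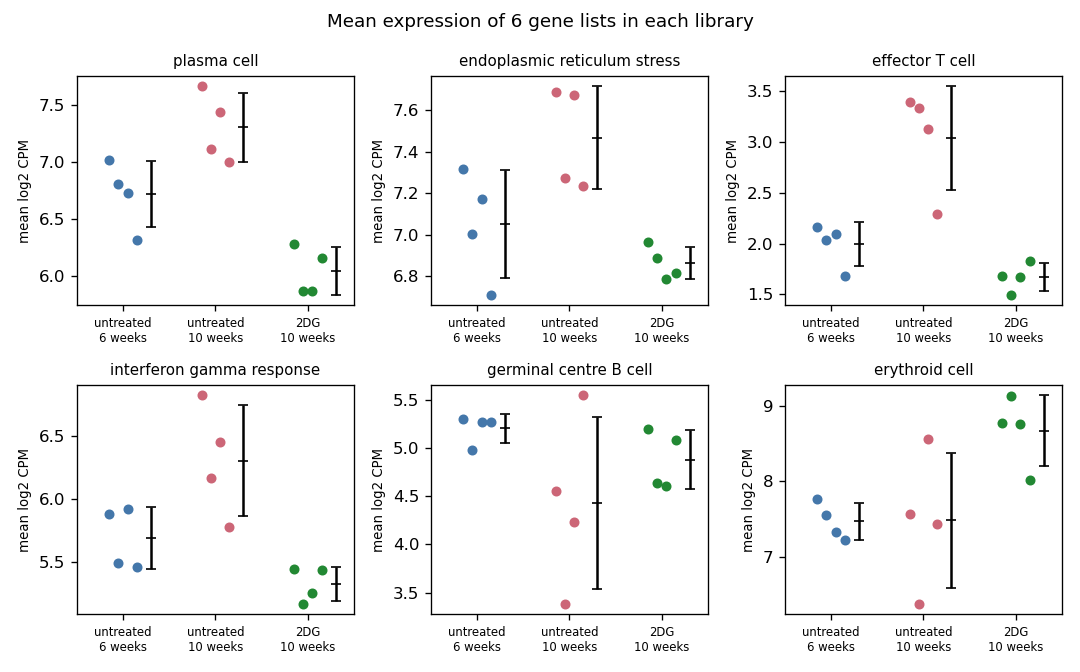
Mean log2 CPM of the tested members of 6 gene lists in each library, by group; points are libraries, black bars give the mean and SD of 4 libraries, and the vertical axes do not start at 0. The 4 libraries with 2DG lie below every untreated 10-week library for the plasma cell, endoplasmic reticulum stress, effector T cell and interferon gamma lists.

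The preset-correlation set test called 16 of 29 lists with 2DG, 5 higher and 11 lower, an estimated correlation 0 and fry 13. Fry called plasma cell, immunoglobulin constant region, effector T cell and interferon gamma lists lower (fry adjusted p 0.00101 to 0.00658). Also lower were endoplasmic reticulum stress, regulatory T cell, age-associated B cell, immediate early, glycolysis and follicular helper T cell lists (0.015 to 0.0283). Marginal zone B cell, dendritic cell and erythroid lists were higher (0.00291 to 0.0428). Fry did not call the other preset lists, type I interferon, cell cycle and megakaryocyte (0.112 to 0.508). The number of genes was 514 without 2DG replicate 11, 515 without 2DG replicate 10, 725 without untreated replicate 5 and 2209 without untreated replicate 8. It was 581, of which 75 were higher and 506 lower, with only these groups in the fit, 83 against a fold change of 1.5 and 2304 with DESeq2. With only these groups in the fit Cd209a, Efnb1, Fcgr1, Hba-a2, Igfbp5, Pfkfb3, Pkm, Scand1 and Slc6a4 also lost their calls (edgeR adjusted p from 0.0516 to 0.11). Without a filter on low counts Cd209a, Fcgr1, Igfbp5, Ly6c2, Scand1 and Slc6a4 did (edgeR adjusted p from 0.0554 to 0.117), and with limma's voom and quality weights Fcgr1, Hba-a2, Ly6c2 and Slc6a4 (adjusted p from 0.053 to 0.145).

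The third comparison set 2DG-treated spleens at 10 weeks against untreated spleens at 6 weeks. Il33, an alarmin cytokine, fell from 47.5 ± 3.98 to 25.5 ± 4.76 CPM (log2 change -0.90, SE 0.15, edgeR adjusted p = 0.0487), and Dnm3, a dynamin, from 14.9 ± 3.15 to 6.76 ± 1.58 CPM. Aldh1a7, an aldehyde dehydrogenase, rose from 2.58 ± 0.726 to 7.67 ± 1.86 CPM. Acyp2 and Syngr1 rose with log2 changes of 1.15 and 1.06, and Slco4a1 fell by 0.96. These were the 3 largest rises and the 3 largest falls among called genes with average log2 CPM of at least 2, no overlap and no predicted name; the 5 called genes at lower levels, Gm5535, AU015791, Gm38171, Gprin2 and Gm15893, chosen after their values were seen, fell further (-3.70, -3.40, -1.73, -1.62 and -1.30). In all 24 genes passed, 7 higher and 17 lower (edgeR). No list member passed over all genes tested. All 14 plasma cell genes had negative changes, with a median of -0.62 and 11 lower over the list alone, and all 19 erythroid genes had positive changes, with a median of 1.24 and 15 higher over the list alone (adjusted p = 0.755 for each list with an estimated correlation). Globin genes took 0.598 ± 0.121% of counts at 6 weeks and 1.37 ± 0.369% with 2DG, and mitochondrial genes 1.95 ± 0.0701% and 2.17 ± 0.0318%, each higher in 4 of 4 libraries (two-sided exact permutation p = 0.0286 and 0.0571 after adjustment for each, which misses the threshold). The preset-correlation set test called 9 lists: erythroid, cell cycle and oxidative phosphorylation higher (3), and plasma cell, immunoglobulin constant region, regulatory T cell, type I interferon, interferon gamma and endoplasmic reticulum stress lower (6), each with adjusted p = 0.755 with an estimated correlation, and 0 with an estimated correlation; fry called 0.

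This count differed between fits. With only the compared groups in the fit edgeR called 1367 genes, 803 higher and 564 lower; voom with quality weights called 1644, 938 higher and 706 lower, and DESeq2 902, of which 542 were higher and 360 lower. It was 1 without 6-week replicates 1, 3 or 4 or 2DG replicate 11, 2 without 6-week replicate 2 or 2DG replicate 10, and 6 without 2DG replicate 9. Without untreated 10-week replicates 5, 6 and 7 in turn it was 51, 344 and 354, and without 2DG replicate 12 it was 289. Il33, Dnm3, Aldh1a7, Acyp2, Syngr1 and Slco4a1 each lost the call without any 1 of the 6-week replicates, 2DG replicate 9 or 2DG replicate 11, all but Slco4a1 also without 2DG replicate 10, and Aldh1a7 without untreated 10-week replicate 8 (edgeR adjusted p up to 0.184). Under the stricter filter Il33, Aldh1a7 and Syngr1 lost the call (edgeR adjusted p = 0.0552, 0.0534 and 0.0534), and so did Il33 with median-of-ratios size factors (0.0517).

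Genes that changed with age and changed the opposite way with 2DG were counted last. The count was 1, Cd8a, against 0.0216 for independent lists. Both contrasts use the same untreated 10-week libraries, and 20 simulations with unchanged groups gave 0 to 6 such genes, with a mean of 1.4. Each gene was drawn independently there, while the correlation estimated within the gene lists had a median of 0.312. The simulated ranges may therefore be too narrow. Across genes, which are not independent replicates, the log2 changes of the contrasts had a correlation of -0.71, and a simulated one of -0.705; the covariance was -0.132, against -0.0448 simulated, a difference of -0.0875. With the untreated 10-week libraries split, 2 for each contrast, the correlation lay between -0.438 and -0.271, the covariance between -0.0889 and -0.0606 and the count between 0 and 25 over the 6 assignments. The count was 1047 without untreated 10-week replicate 8, 1 without 2DG replicate 10 and 0 without any 1 of the other 10 libraries. It was 80 with no filter on low counts and 477 with DESeq2.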

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

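All tests in this part were chosen after the values were seen, except the counts over other splits of the libraries and the search for single libraries far from the rest of their group. In that search, a library stood out where its gap to the nearest of the other 3, as a share of the group's range, passed the critical value of Dixon's test. Of 300 group values 11 did so, against 15 expected by chance.

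In the untreated 10-week group, replicate 8 was low for Cxcr3 (gap 0.993 of the range) and high for the mitochondrial share of counts (0.864). Replicate 5 was low for Tlr7 (0.883) and high for Fas (0.842) and for the follicular helper T cell list (0.913), and replicate 6 was high for the regulatory T cell list (0.872). With 2DG, replicate 10 was low for Aldoa (0.977) and high for Cd8a (0.879), replicate 11 was low for the type I interferon list (0.879) and replicate 12 was high for the fatty acid oxidation list (0.882). Replicate 2 at 6 weeks was low for the germinal centre B cell list (0.886).

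The first pattern is that 1 gene passed with age; 4 of 35 splits of the 8 untreated libraries gave at least as many, the highest other split 16, so chance is not excluded. Fewer counts and a swap between the untreated groups are argued against, since the median total at 10 weeks was 1.07 times that at 6 weeks and 0 of the 6-week libraries lay nearer to untreated 10-week replicates 5, 6 and 7 than to their own group. Wide spread in the untreated 10-week group stays open, as does the stage of disease, which was not tested: its coefficient of variation was 1.9 times that of the next group, and 0.25 without replicate 8 against 0.242 with it, but without that library 1563 genes passed (edgeR). A 6-week spleen labelled as replicate 8 also stays open: the mean share of genes at which it lay outside the range of 3 6-week libraries was 0.454, against 0.403 to 0.574 for a left-out 6-week library and 0.644 to 0.745 for replicates 5, 6 and 7, and over 497 genes called without it its median place between the 6-week mean (0) and that of replicates 5, 6 and 7 (1) was 0.188, against -0.101 to 0.295 for held-out 6-week libraries, 3 of them on 6, 9 and 19 genes, and 0.595 to 0.939 for held-out replicates 5, 6 and 7. Replicate 8 had Cd8a, a gene fixed in advance, at 37.7 CPM, below the 6-week range of 56.4 to 70.7 CPM. Its immunoglobulin share, a planned measure, was 5.11%, above the 6-week range of 2.79 to 4.94%. Il15 and Tlr7, also fixed in advance, lay inside the 6-week ranges, at 5.50 CPM in 5.03 to 5.61 and 211 CPM in 185 to 257. Eomes and Icos, at 5.07 and 6.99 CPM, lay above the 6-week ranges of 2.06 to 3.01 and 3.71 to 5.18 CPM. Eomes and Icos were named with that library included. Cd8b1, chosen after its values were seen, stood at 4.135 CPM, above the 6-week range of 1.913 to 2.455 CPM.

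The second pattern is the fall of plasma cell genes with 2DG. It lies within a comparison where 1 of 35 splits, the real one, gave as many as 1376 genes and the highest other gave 474. That is the smallest share these splits allow and was not adjusted over the counts tested. Chance is therefore argued against for that count, but not excluded. Immunoglobulin counts taking a share of each library are argued against. Before TMM scaling, the loss of that share shifts every other gene upward, by 0.0958 on the log2 scale. That direction was fixed once the share was known to fall. With immunoglobulin genes removed before the fit the plasma cell median log2 change was -1.23, against -1.22 with them. One common fall of all plasma cell transcripts stays open: the mean of the 12 immunoglobulin constant region genes minus that of 14 plasma cell genes changed by -0.434 on the log2 scale (two-sided exact permutation p = 0.0286, lower in 4 of 4 libraries), but other B cells also express genes of both lists. For 4 immunoglobulin G genes, chosen after their values were seen, that difference was -2.35, which tests nothing further. Fewer plasma cells and less transcript per cell both stay open, since whole spleen was measured.

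The third pattern is the higher level of erythroid genes with 2DG, whose list mean differed by 1.18 on the log2 scale (two-sided exact permutation p = 0.0571). Blood left in the spleen stays open beside more erythroid precursors. The 5 precursor genes changed by 0.823 to 1.098, with a median of 0.874, and the 4 globin genes by 0.96 to 1.257, with a median of 1.07. The higher level was therefore not confined to globin genes. The precursor mean had an exact permutation p of 0.0571, the same as the erythroid list mean. That p judges whether a rise was there and cannot separate its sources. Low globin in untreated replicate 6, 0.132% of counts (Wilson 95% interval 0.13 to 0.133%), also stays open: without that library the erythroid median was 0.767 rather than 1.04 and the list mean had an exact permutation p of 0.143. Against 6-week spleens, a comparison that does not use replicate 6, the list mean was 7.47 ± 0.242 log2 CPM at 6 weeks and 8.67 ± 0.469 with 2DG (n = 4; two-sided exact permutation p = 0.0286, higher in 4 of 4 libraries), which that library cannot give, but this does not settle the difference at 10 weeks.

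Chance was not excluded for the counts of called gene lists. With age, 4 of 35 splits gave at least the real 16 lists, the highest other 17. For 2DG against untreated spleens at 10 weeks, 5 of 35 gave at least 16, the highest other 18, and for 2DG against 6 weeks 12 of 35 gave at least 9, the highest other 14. For the 24 genes of 2DG against 6 weeks, 1 of 35 splits, the real one, was as large, with 0 as the highest other. That is the smallest share these splits allow and was not adjusted over the counts tested. Chance is therefore argued against for that count, but not excluded. The single opposite change was reached in 1 of 50 regroupings of the 12 libraries, the real one, with 0 as the highest other, but simulations of unchanged groups reached up to 6, so it is not beyond what shared libraries give.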

How the results depend on the processing

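The counts without untreated 10-week replicates 6 and 8 and those at an adjusted p under 0.1 were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. With age, where 1 gene passed, DESeq2 called 682 and edgeR 102 with no low-count filter, 0 with only the compared groups, 0 against a fold change of 1.5, 2303 without replicates 6 and 8 and 211 at 0.1; leaving out 1 library gave 0 to 1563. For 2DG against untreated spleens, where 1376 passed, the counts were 2304 with DESeq2, 581 with only the compared groups, 83 against the fold change, 3193 without replicates 6 and 8 and 2578 at 0.1; leaving out 1 library gave 514 to 2209. For 2DG against 6 weeks, where 24 passed, they were 902 with DESeq2, 98 with no filter, 1367 with only the compared groups, 1644 with voom, 0 against the fold change, 758 without replicates 6 and 8 and 428 at 0.1; leaving out 1 library gave 1 to 354. The opposite change of 1 gene became 477 with DESeq2, 80 with no filter, 0 with only the compared groups, 1601 without replicates 6 and 8, 25, 14, 0, 0, 0 and 0 with split controls, and 0 to 1047 with 1 library left out. With an estimated correlation 0 lists were called in each comparison, and fry called 3 with age and 0 for 2DG against 6 weeks. Median-of-ratios size factors, removal of immunoglobulin genes and the stricter filter kept each count run under them within 1.5 times. A stricter threshold explains fewer calls and a looser one more by construction. For 2DG against 6 weeks the untreated 10-week libraries enter only through the filter, the normalization and the spread shared by all groups. Median-of-ratios size factors gave 22 genes there, the stricter filter 18 and no filter 98, against 1367 with only the compared groups. Changing the method of filter or normalization over all 12 libraries thus gave far smaller rises. Those settings still used the untreated 10-week libraries, and the fit of only the compared groups changed filter, normalization and spread together. The part of the shared spread was therefore not separated. For the other settings the cause was not tested either.

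Of 43 named genes called with 2DG at 10 weeks, 28 passed in every fit that left out 1 library, 27 in these and in every other setting but the fold threshold, and 14 with that threshold; none reversed. Leaving out 1 library, the immunoglobulin share differed by 4.26 to 6.12 points with age, -7.48 to -5.62 for 2DG at 10 weeks and -1.72 to -0.999 for 2DG against 6 weeks. The top 10 genes differed by 2.34 to 3.57 and -3.49 to -2.26 with age and for 2DG at 10 weeks, globin for 2DG against 6 weeks by 0.656 to 0.942, and the mitochondrial share by -0.23 to -0.0657 with age, 0.28 to 0.445 for 2DG at 10 weeks and 0.192 to 0.247 for 2DG against 6 weeks. The exact p of the shares, before adjustment, went from 0.0286 to 0.0571 without any 1 of the 6-week replicates for immunoglobulin and the top 10 genes with age and globin for 2DG against 6 weeks, without any 1 of the 2DG replicates for immunoglobulin and the top 10 genes for 2DG at 10 weeks, and without 2DG replicates 9, 10 or 12 for mitochondrial genes against 6 weeks. It fell to 0.0286 without untreated 10-week replicate 8 for mitochondrial genes with age and for 2DG at 10 weeks, and without 6-week replicate 4 for immunoglobulin for 2DG against 6 weeks. Where it rose, the compared groups did not overlap, with or without the library left out. With unequal group sizes such separation gives an exact permutation p of 0.0286 or 0.0571. The rise therefore comes with the unequal sizes and not with an overlap.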

Other observations

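The tests in this part were chosen after the result was seen, and so were the genes named. Of the 24 genes that differed between 2DG-treated spleens and 6-week spleens, 21 also changed the same way against untreated 10-week spleens. Arid3a, a DNA-binding protein, stood at 78.2 ± 4.56 CPM at 6 weeks, 84.1 ± 7.51 CPM untreated at 10 weeks and 45.7 ± 2.02 CPM with 2DG (n = 4 each; edgeR adjusted p = 0.00144 against 6 weeks and 0.000329 against 10 weeks). Il33 stood at 47.5 ± 3.98, 54.5 ± 11.2 and 25.5 ± 4.76 CPM. Independent lists would share 1.04 genes, and 20 simulations in which unchanged groups shared the 2DG libraries gave at most 1. The simulations drew each gene independently, so unchanged groups of real genes, which move together, could give larger overlaps. With the 2DG libraries split, 2 against each untreated group, the overlap was 0 in all 6 assignments, where edgeR called 0 to 13 genes against untreated 10-week spleens and 5 to 1454 against 6 weeks (0 to 0.0641 expected for independent lists). Against untreated 10-week spleens these fits called so few genes that an overlap of 0 cannot decide the question, and where 0 were called none was possible. For the 21 genes the part that comes from the shared 2DG libraries therefore stays open. Across genes, which are not independent replicates, the covariance of the log2 changes in the 2 comparisons was 0.107, against 0.0174 in the simulations, a difference of 0.0902. The covariance was 0.0773 to 0.102 over the 6 assignments with no shared library. Across all genes, these values argue against shared 2DG libraries as the main source of the covariance. They do not cover the 21 genes as a set.

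The spread of immunoglobulin variable gene usage gave no difference past the threshold. The effective number of Ighv genes was 27.0 ± 3.56 in untreated spleens at 10 weeks and 32.2 ± 5.88 with 2DG (n = 4; two-sided exact permutation p = 0.171, 0.686 after adjustment over 6 tests). That of Igkv genes was 31.8 ± 6.65 and 29.4 ± 3.21 (exact permutation p = 0.6, adjusted 0.72). Ighe, the IgE constant region, stood at 7.07 ± 4.52, 25.0 ± 3.76 and 22.4 ± 9.21 CPM at 6 weeks, untreated at 10 weeks and with 2DG (edgeR adjusted p = 0.111 with age and 0.866 for 2DG at 10 weeks).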
